A study of Sus scrofa with 8 samples.

How the data were processed

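RNA-seq libraries from condylar cartilage cells of the pig temporomandibular joint were analysed, 4 from control joints and 4 from joints with a model of osteoarthritis. Per the labels' protocols, the disc of the joint was perforated with a 5.0 mm biopsy punch. Per the same protocols, total RNA was extracted with a micro-scale column kit, ribosomal RNA was depleted with a probe kit (QIAseq FastSelect), and libraries were made with a kit that keeps strand (NEBNext Ultra II Directional). Groups and replicate numbers were taken from the sample titles. The labels call the samples biological replicates and do not say that each came from a separate animal, so p-values measure the spread between these samples.

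The authors' deposited table holds, for 18898 genes, estimated counts per library, TPM, log2 of TPM and effective gene lengths. Per the submitters' processing notes, the tools were Trim Galore 0.6.7, STAR 2.7.9a, StringTie 2.1.0, Salmon 1.1.0, DESeq2 1.26.0 and MultiQC 1.13, with the build Sscrofa11.1. The notes give neither the role of each tool nor the order. The deposited estimated counts are whole numbers in the table, and were rounded as a safeguard. The filter that left these genes is not given in the sources used here. The deposited TPM values equal the counts divided by the effective lengths and rescaled, with a largest relative difference of 9.6e-15, and were used for that check only. The 8 columns of log2 TPM were not used. The strand setting of the quantification is not given in the sources used here. Estimated counts share ambiguous reads between near-identical copies, so values of ribosomal protein, small nucleolar RNA and signal recognition particle RNA genes are uncertain between copies.

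Total estimated counts were 13214075, 14990171, 13028760 and 19710638 in control replicates 1 to 4, and 14753285, 11354200, 21895845 and 25412939 in osteoarthritis replicates 1 to 4. Gene symbols came with the file for 12365 genes. A further 558 were added by gene identifier and 566 through Entrez identifiers from reference tables, and no coordinates are given.

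Genes were filtered with filterByExpr, scaled by TMM and compared with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with the group as the sole term. P-values were adjusted by Benjamini-Hochberg over the 16020 genes tested, and an adjusted p under 0.05 is called changed. Fold changes are log2 values of osteoarthritis against control, followed by ± their standard error, which was taken as the size of the fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM, as mean ± SD with n = 4 per group. For a gene at 0 in a group, folds are lower bounds against a floor of 3 counts over that group. On simulated counts for this comparison, 3 runs with 200 of 16020 genes changed, the test recovered 6.33% of genes changed 2-fold, 68.7% of those changed 4-fold and 92.7% of those changed 8-fold. In these runs 5.39% of its calls were unchanged genes. The changed genes were drawn from those with a mean log2 CPM of at least 2. The simulated libraries were independent and had no shift of composition between groups. Recovery of lower genes and the error rate of the real comparison may therefore differ.

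A total of 27 gene lists, covering pathways and cell types that the tissue could hold, were fixed before the data were examined and tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 27 lists. List medians are over tested members, and each count of changed members is also given adjusted over the list alone. An estimated correlation and fry were alternatives. Library measures (total count, detected genes and shares of counts in gene classes) were compared with an exact two-sided permutation test over 70 assignments, whose smallest p is 0.0286, adjusted over 11 measures. The share of short non-coding and ribosomal RNA genes, the protein-coding share, the scaling factor and the fragment length were added to the planned measures after seeing the data.

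The genes to be named were set by a rule fixed before the data were examined. It took the 8 largest increases and the 8 largest decreases among changed genes with a symbol, a mean log2 CPM of at least 2 and no overlap of groups. It also allowed up to 4 members of each list with the smallest p, of which 2 were taken for a called list and 1 for any other, and 19 genes chosen for the Wnt, cartilage and inflammation questions. Genes named outside this rule are said to have been chosen after their values were seen. No value is given for IL6, which was not analysed here. Of the genes this rule selects, 1 is not reported here. Alternatives covered other scalings (RLE, upper quartile, library size alone), filters, DESeq2 1.42.0, limma-voom with and without sample weights, a test against a 1.5-fold change, the replicate number as a block, 1 surrogate variable (sva 3.50.0), removal of mitochondrial, rRNA and haemoglobin genes, other thresholds and each library left out in turn. After seeing the data, summing controls 1 and 3, effective-length offsets and a fit on protein-coding genes alone were added.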

Results

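The transcriptome of pig condylar cartilage cells, from the surface of the jaw joint that faces the articular disc, was measured by rRNA-depleted, strand-specific RNA-seq in 4 control and 4 osteoarthritis samples. In the osteoarthritis group the disc of the joint had been perforated surgically. Total estimated counts ranged from 11354200 to 25412939 per library. Group means were 15235900 ± 3111430 in controls and 18354100 ± 6437800 in osteoarthritis (SD, n = 4 each; exact permutation p = 0.40), a difference below the osteoarthritis SD and about equal to the control SD. The comparison asks which genes differ between the groups, with the title of the series pointing to Wnt inhibition and chondrocyte identity.

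Transcripts of PRG4, CLEC3A and HHIP were higher in osteoarthritis, and those of KRT5, KRT14 and COL17A1, which basal epithelial cells express, were far lower. PRG4 (ENSSSCG00000029449), which encodes the joint lubricant lubricin, rose from 3.32 ± 1.43 to 25.7 ± 9.59 CPM, and HHIP (ENSSSCG00000009045), a hedgehog-binding inhibitor of that pathway, rose from 6.29 ± 2.11 to 41.0 ± 14.5 CPM. In the opposite direction, the basal keratins KRT5 (ENSSSCG00000000248) and KRT14 (ENSSSCG00000017448) fell from 110.6 ± 57.0 and 93.3 ± 52.2 CPM to 0.509 ± 0.203 and 0.428 ± 0.253 CPM. Of 16020 genes tested, 99 changed at an adjusted p under 0.05 (edgeR quasi-likelihood test), 36 higher and 63 lower in osteoarthritis. An unadjusted p under 0.05 was found for 2431. The groups did not overlap in any of the 99 genes; among all genes tested they did not overlap in 1795, where chance leaves 2 of 70 assignments of the samples without overlap. A pair of gene models among the 99 had identical values in every library. With library size as the only scaling, 186 genes were higher and 28 lower, 57 of them shared with the 99, and the median log2 fold change of all genes moved from 0.0049 to 0.65. The count of changed genes was 844 by DESeq2, 3329 by limma-voom with sample weights, 31 against a 1.5-fold change, 7 with 1 surrogate variable and 31 with the closest pair of libraries, controls 1 and 3, summed. Leaving out control replicates 1 to 4 gave 31, 52, 28 and 152, and leaving out osteoarthritis replicates 1 to 4 gave 17, 33, 90 and 14.

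The 8 largest increases selected by the fixed rule were led by AHRR, a repressor of the aryl hydrocarbon receptor, with a log2 fold change of 4.33 ± 0.74 (edgeR adjusted p = 0.045). CLEC3A, a C-type lectin of cartilage, rose by 4.18 ± 0.66 on the log2 scale, from 12.03 ± 3.19 to 220.0 ± 152.5 CPM (edgeR adjusted p = 0.037). CRISPLD1 followed at 3.01 ± 0.46, PRG4 at 2.96 ± 0.39 (edgeR adjusted p = 0.018) and HHIP at 2.69 ± 0.33 (edgeR adjusted p = 0.014). Next came the extracellular matrix glycoprotein gene PAPLN at 2.58 ± 0.42 and PAQR9 at 2.46 ± 0.32. TRPV4, a calcium channel that chondrocytes use to sense load, rose by 2.37 ± 0.41, from 44.3 ± 10.05 to 229.2 ± 119.6 CPM (edgeR adjusted p = 0.044). Each of these 8 was higher in all 4 osteoarthritis libraries than in any control. With a single library left out in turn, HHIP lost its call without osteoarthritis replicate 1 or 4 and PRG4 without control replicate 3 or osteoarthritis replicate 1, 2 or 4 (adjusted p over all alternatives, tools included, from 6.8e-11 to 0.12 and from 4.1e-10 to 0.21). CRISPLD1, PAPLN and PAQR9 kept theirs only without control replicate 4 or osteoarthritis replicate 3, AHRR only without control replicate 4, and CLEC3A and TRPV4 only without osteoarthritis replicate 3. AHRR was at 4.98 without control replicate 4 and 3.56 without osteoarthritis replicate 4. In the order CRISPLD1, PAPLN, PAQR9, AHRR, CLEC3A and TRPV4, these genes had adjusted p over all alternatives of up to 0.24, 0.24, 0.10, 0.16, 0.28 and 0.31.

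Transcripts of the basal epithelial genes KRT5 and KRT14 were present in all 4 control libraries and nearly absent from the osteoarthritis libraries. KRT5 fell by 7.84 ± 0.57 and KRT14 by 7.89 ± 0.65 on the log2 scale (edgeR adjusted p = 0.0029 for both), and both were called in each of the 8 fits with a library left out. COL17A1, a hemidesmosomal collagen, fell by 4.22 ± 0.52 (edgeR adjusted p = 0.014; up to 0.092 over the alternatives, and lost without osteoarthritis replicate 2 or 4). In the list for epithelium, 3 of 7 tested members fell over all genes tested (KRT5, KRT14 and ESRP1, the last chosen after its values were seen), 6 of 7 adjusted over the list alone, and the list median was -1.56 with a mean of -3.98. The list was called (camera adjusted p = 3.1e-22) and held with an estimated correlation (adjusted p = 0.028). Further epithelial genes among the 99, chosen after their values were seen, included PERP, a desmosomal gene, at -4.68 ± 0.64, and TP63, the transcription factor of basal epithelial cells. SERPINB5 and PKP1, chosen likewise, had 205 and 141 counts over the controls and 1 and 7 over osteoarthritis. TP63 had 99, 24, 62 and 55 counts in control replicates 1 to 4 and 0, 0, 0 and 1 in osteoarthritis replicates 1 to 4.

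**Figure D1:**
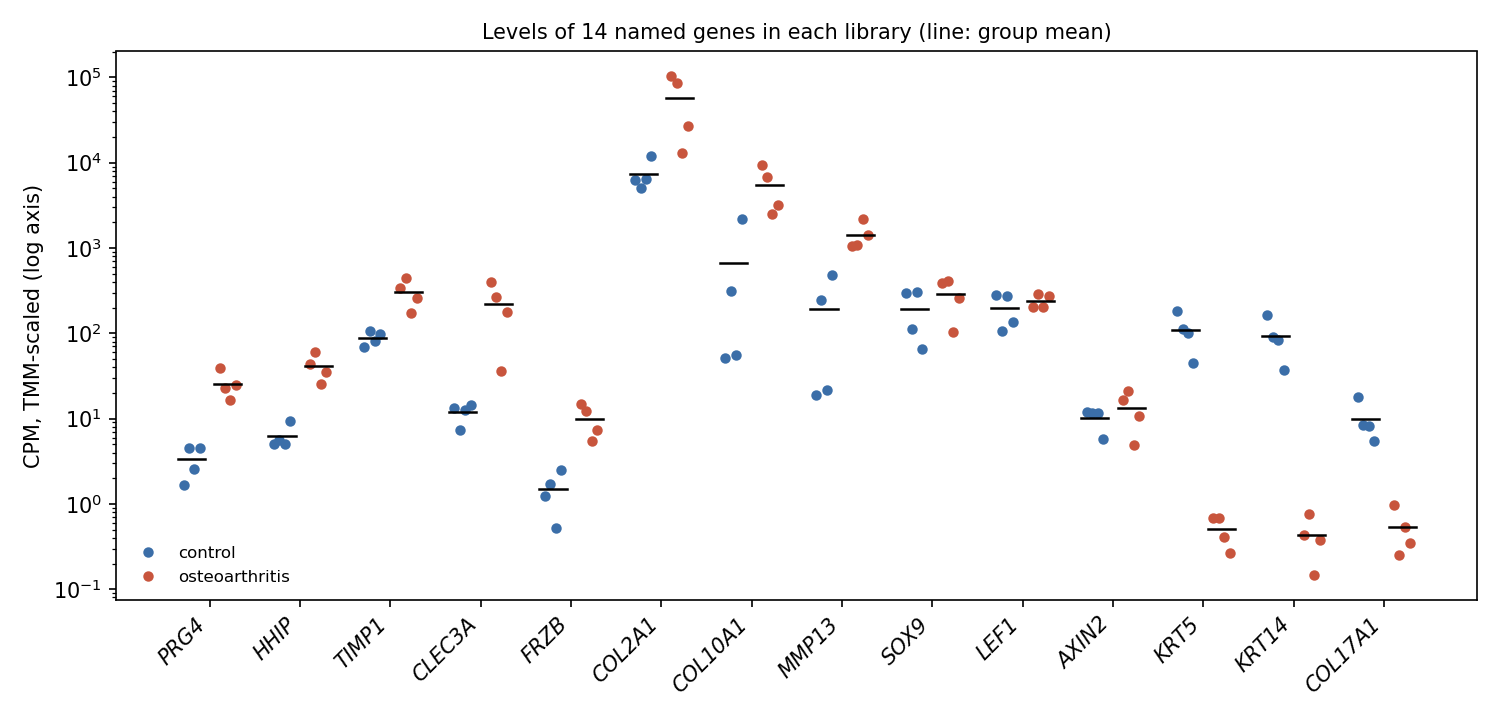
TMM-scaled CPM, on a log axis, of 14 named genes in each of the 4 control and 4 osteoarthritis libraries, with a line at each group mean. PRG4, HHIP, TIMP1 and CLEC3A lie higher in all 4 osteoarthritis libraries, SOX9, LEF1 and AXIN2 overlap between groups, and KRT5, KRT14 and COL17A1 lie lower in osteoarthritis.

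Cartilage matrix genes were measured higher as a list in osteoarthritis (camera adjusted p = 2.9e-17 at the preset correlation). This call was lost with an estimated correlation (adjusted p = 0.17 with an estimated correlation) and by fry (adjusted p = 0.055). In the list for chondrocyte identity and cartilage matrix, all 22 tested members had a fold change above 0, with a median of 2.32. By edgeR 0 passed over all genes, 16 had an unadjusted p under 0.05 and 15 passed adjusted over the list alone; DESeq2 called 14, limma-voom 2 and limma-voom with sample weights 15. COL2A1, the main collagen of cartilage, was measured at 7413 ± 3073 CPM in controls and 57200 ± 43924 CPM in osteoarthritis (2.95 ± 0.79, edgeR adjusted p = 0.14), and ACAN, the main cartilage proteoglycan, at 1950 ± 1309 and 7830 ± 4953 CPM (2.01 ± 0.78, edgeR adjusted p = 0.27). SCRG1 (3.49 ± 0.62, edgeR adjusted p = 0.0502) and COL9A1 (3.44 ± 0.66, edgeR adjusted p = 0.059) also missed the threshold. SOX9, the transcription factor of chondrocyte identity, overlapped between groups at 194.1 ± 123.5 and 289.1 ± 138.9 CPM (0.57 ± 0.57, edgeR adjusted p = 0.68).

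Chondrocyte hypertrophy genes were also measured higher as a list (camera adjusted p = 4.3e-11; adjusted p = 0.17 with an estimated correlation). All 11 of 11 tested members were above 0, with a median of 1.95, 0 passing over all genes by edgeR, 9 at an unadjusted p under 0.05 and 9 passing adjusted over the list alone. DESeq2 called 9, limma-voom 0 and limma-voom with sample weights 9. PANX3, a channel protein of prehypertrophic chondrocytes, was measured at 67.8 ± 28.7 and 402.9 ± 200.8 CPM (2.57 ± 0.50, edgeR adjusted p = 0.064), and SLC13A5, a citrate transporter, at 1.75 ± 0.36 (edgeR adjusted p = 0.076). COL10A1, the collagen of hypertrophic cartilage, had 657.7 ± 1042 CPM in controls and 5396 ± 3175 CPM in osteoarthritis (3.04 ± 1.22, edgeR adjusted p = 0.29), and MMP13, a collagenase, 193.2 ± 222.1 and 1435 ± 524.5 CPM (2.89 ± 1.00, edgeR adjusted p = 0.23). In control replicates 1 to 4, COL10A1 was at 50.7, 315, 55.2 and 2210 CPM and MMP13 at 19.0, 247, 21.7 and 485 CPM. Controls 1 and 3, the closest pair of libraries, were thus the lowest for both genes. Without control replicate 4, the highest control for both, COL10A1 was at 5.27 and MMP13 at 3.93, still without a call (edgeR adjusted p = 0.053 and 0.12). That fit gives controls 1 and 3 more weight.

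Among secreted Wnt antagonists, which bind Wnt proteins or their receptors outside the cell, 0 of 12 passed over all genes by edgeR, and FRZB alone had an unadjusted p under 0.05 and passed adjusted over the list alone. DESeq2 called 1 member, limma-voom 0 and limma-voom with sample weights 5. FRZB was measured at 1.496 ± 0.83 CPM in controls and 10.02 ± 4.31 CPM in osteoarthritis without overlap (2.72 ± 0.49, edgeR adjusted p = 0.0502; 1.7e-05 to 0.23 over the alternatives). WIF1 (1.06 ± 1.03), SOST (0.85 ± 1.42), SFRP1 (0.44 ± 0.51), SFRP2 (0.38 ± 1.102) and DKK3 (-0.96 ± 0.80) overlapped between groups, with edgeR adjusted p from 0.61 to 0.91. In control replicates 1 to 4, WIF1 was at 2.06, 31.0, 2.90 and 102.6 CPM and SOST at 0.153, 24.7, 0.176 and 28.1 CPM. SFRP2 was at 149.5, 7.56, 162.6 and 12.8 CPM and DKK3 at 223.1, 22.2, 232.7 and 23.3 CPM. Controls 1 and 3 were thus lower than controls 2 and 4 for WIF1 and SOST, and higher for SFRP2 and DKK3. WIF1 was at 2.65 and SOST at 1.61 without control replicate 4, SOST at -0.72 without osteoarthritis replicate 3 and SFRP2 at -0.50 without osteoarthritis replicate 2. The list median was 0.41, with the mean log2 CPM of the list lower in all 4 controls than in every osteoarthritis library. The list was not called by camera (adjusted p = 0.064; adjusted p = 0.25 with an estimated correlation). It was called by fry (adjusted p = 0.045), and by camera without control replicate 4 or osteoarthritis replicate 3 (adjusted p = 0.042 and 0.022). In the other fits with a library left out it was not called (adjusted p of up to 0.15). Its median was 0.085 without osteoarthritis replicate 2, 0.24 without osteoarthritis replicate 4 and 0.63 without osteoarthritis replicate 1. LGR5, a receptor of R-spondins, was too low to be tested, with 0, 0, 0 and 2 counts in control replicates 1 to 4 and 6, 4, 5 and 4 counts in osteoarthritis replicates 1 to 4.

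Canonical Wnt target genes showed no call, with 0 of 14 members passing over all genes or adjusted over the list alone by edgeR, and 1 higher and 4 lower at an unadjusted p under 0.05. DESeq2 called 1, limma-voom 0 and limma-voom with sample weights 6. The list had a median of -0.29 (camera adjusted p = 0.48; adjusted p = 0.76 with an estimated correlation). With 1 surrogate variable the median turned to 0.25, without a call. Relative to all genes it was -0.29, and -0.40 with library size as the only scaling. The median was -0.15 and -0.11 without control replicates 1 and 3, -0.12 without osteoarthritis replicate 3, and -0.44 without control replicate 4 or osteoarthritis replicate 2. AXIN2 (0.37 ± 0.43) and LEF1 (0.27 ± 0.35) overlapped between groups, as did NKD2, an inhibitor induced by the pathway (-2.16 ± 0.74), with edgeR adjusted p of 0.73, 0.75 and 0.23. NKD2 was at -1.34 without control replicate 4. CTNNB1, which encodes beta-catenin, was at 192.7 ± 32.6 and 246.1 ± 42.6 CPM (0.35 ± 0.22, edgeR adjusted p = 0.49), and RUNX1, a transcription factor, at 98.1 ± 35.4 and 111.1 ± 26.6 CPM (0.18 ± 0.29, edgeR adjusted p = 0.81). Wnt ligands and receptors were called higher as a list (31 members, median 0.24, camera adjusted p = 0.0046; adjusted p = 0.17 with an estimated correlation), with 0 members passing over all genes by edgeR, 8 at an unadjusted p under 0.05 and 6 adjusted over the list alone. The median was 0.15 without osteoarthritis replicate 3 and 0.40 without control replicate 4, both with the call kept. DESeq2 called 7, limma-voom 0 and limma-voom with sample weights 13. WLS, which carries Wnt proteins to the cell surface, was at 19.1 ± 3.13 and 39.8 ± 7.39 CPM (1.05 ± 0.21, edgeR adjusted p = 0.064), and the receptor FZD7 at 5.75 ± 0.24 and 15.03 ± 5.69 CPM (1.38 ± 0.27, edgeR adjusted p = 0.067).

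**Figure D2:**
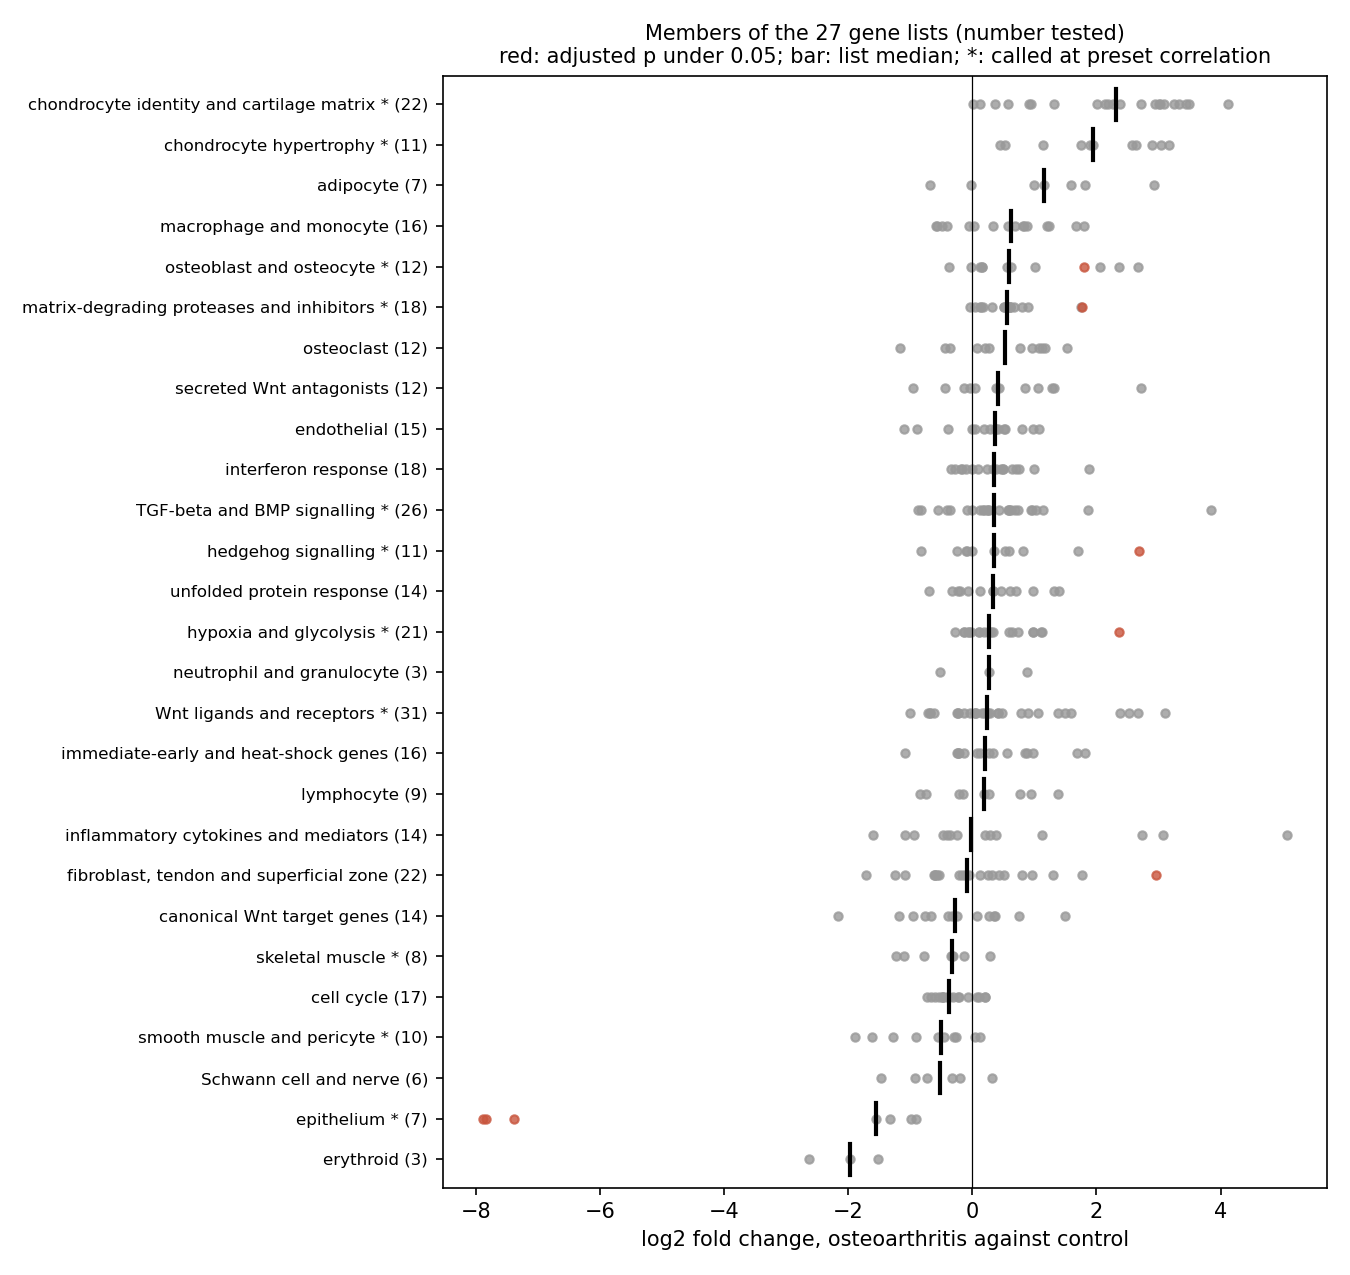
Log2 fold change (osteoarthritis against control, x axis) of every tested member of the 27 gene lists (y axis, number tested in brackets), with the list median as a bar, members at an adjusted p under 0.05 in red and an asterisk for lists called at the preset correlation. The cartilage and hypertrophy lists have medians of 2.32 and 1.95 with no red member, and KRT5, KRT14 and ESRP1 stand far below the other genes.

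Single members rose in lists of signalling and matrix turnover. TIMP1, an inhibitor of metalloproteinases, rose from 89.0 ± 16.8 to 304.7 ± 116.8 CPM (1.77 ± 0.32, edgeR adjusted p = 0.0497), the 1 of 18 members of the protease and inhibitor list to pass over all genes and the 1 adjusted over the list alone. Among fits with a library left out its call held only without osteoarthritis replicate 3, with an adjusted p of up to 0.27 over the alternatives. That list, with 17 members above 0 and a median of 0.56, was called (camera adjusted p = 9.1e-04; adjusted p = 0.17 with an estimated correlation; median 0.34 without control replicate 2), and MMP16 was at 0.90 ± 0.28 (edgeR adjusted p = 0.18). HHIP was the 1 of 11 hedgehog members to pass, and 2 passed adjusted over the list alone. PTCH1, the hedgehog receptor and a target of the pathway, was at 1.71 ± 0.42 (edgeR adjusted p = 0.11), and the list was called with a median of 0.34 (camera adjusted p = 0.044; adjusted p = 0.71 with an estimated correlation). That call was lost under a stricter filter (adjusted p = 0.052) and by fry (adjusted p = 0.35). ADM, a vasodilator peptide induced by low oxygen, rose by 2.36 ± 0.40 (edgeR adjusted p = 0.044) as the 1 of 21 hypoxia and glycolysis members to pass over all genes and the 1 adjusted over the list alone; with a library left out it was called only without control replicate 2 or osteoarthritis replicate 3. EGLN3, a prolyl hydroxylase, was at 1.12 ± 0.32 (edgeR adjusted p = 0.16). The hypoxia list had a median of 0.27 (camera adjusted p = 0.022; adjusted p = 0.71 with an estimated correlation; adjusted p = 0.43 by fry). Both calls were lost without control replicate 2 or 4 or osteoarthritis replicate 1 or 2, with medians in that order of 0.21, 0.044, 0.17 and 0.11 for hypoxia and 0.052, 0.22, 0.32 and -0.0034 for hedgehog. The called medians rose to 0.44 for hypoxia without control replicate 1 or 3, and to 0.59 for hedgehog without control replicate 3 or osteoarthritis replicate 3.

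In the list for TGF-beta and BMP signalling, 0 of 26 members passed over all genes in edgeR, 5 were higher and 1 lower at an unadjusted p under 0.05, and 2 passed adjusted over the list alone. The latter were GDF5, a growth factor of joint formation (3.84 ± 0.71, edgeR adjusted p = 0.053), and LTBP1, which binds latent TGF-beta (0.96 ± 0.23, edgeR adjusted p = 0.10). DESeq2 called 2 members, limma-voom 0 and limma-voom with sample weights 9. The list median was 0.35 (camera adjusted p = 0.021; adjusted p = 0.42 with an estimated correlation), and the call was lost by fry (adjusted p = 0.14) and without osteoarthritis replicate 2. Inflammatory mediators were not called (camera adjusted p = 0.27; adjusted p = 0.71 with an estimated correlation), and their median of -0.022 differed in sign from their mean of 0.56. The median turned to between 0.12 and 0.29 without control replicate 2 or 4 or osteoarthritis replicate 2 or 4. CXCL8, a neutrophil attractant, was at 5.07 ± 1.19 (edgeR adjusted p = 0.10), and at 3.35 without osteoarthritis replicate 3, its highest library. In all, 0 of 14 inflammatory members passed over all genes by edgeR, 4 had an unadjusted p under 0.05 and 2 passed adjusted over the list alone. DESeq2 called 1, limma-voom 0 and limma-voom with sample weights 5.

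Bone markers were uneven among the controls. PDPN, a membrane glycoprotein of early osteocytes, rose from 24.7 ± 4.53 to 86.5 ± 30.5 CPM (1.80 ± 0.29, edgeR adjusted p = 0.037), the 1 of 12 osteoblast and osteocyte members to pass over all genes and the 1 adjusted over the list alone. With a library left out it was called only without osteoarthritis replicate 3, with an adjusted p of up to 0.29 over the alternatives. ALPL, an alkaline phosphatase of mineralising tissue, was at 2.36 ± 0.85 (edgeR adjusted p = 0.25), and at 3.05 without control replicate 4. The list was called with a median of 0.59 (camera adjusted p = 0.0046; adjusted p = 0.17 with an estimated correlation), and the call was lost by fry (adjusted p = 0.076). Its median was 0.26, 0.27 and 1.49 without control replicates 1, 3 and 4 and 0.25 without osteoarthritis replicate 3, with the call kept. BGLAP, the bone protein osteocalcin, which was chosen after its values were seen, had 51, 230, 61 and 6297 counts in control replicates 1 to 4 and 301, 286, 9233 and 2619 in osteoarthritis replicates 1 to 4. The mean log2 CPM of osteoclast genes was 1.00, 6.32, 1.31 and 6.24 in control replicates 1 to 4 and 5.70, 4.93, 6.41 and 5.20 in osteoarthritis replicates 1 to 4. No osteoclast member passed: 0 by edgeR over all genes, adjusted over the list alone or at an unadjusted p under 0.05, and 0 by DESeq2 or limma-voom, against 10 by limma-voom with sample weights. The osteoclast list was not called (median 0.52, camera adjusted p = 0.064; CA2 at 1.52 ± 0.87, edgeR adjusted p = 0.44). It was called without control replicate 2 or 4 or osteoarthritis replicate 4 (camera adjusted p = 0.0023, 0.0072 and 0.022). Its median was -0.11 without osteoarthritis replicate 3. Fibroblast, tendon and superficial zone genes were not called (camera adjusted p = 0.27), with a median of -0.082 and a mean of 0.086. Without control replicate 1 or 3 that list was called higher, with medians of 0.18 and 0.28 (camera adjusted p = 0.033 and 0.021). In it PRG4 was the 1 of 22 members to pass over all genes and the 1 adjusted over the list alone. COL1A1, the main collagen of fibrous tissue, was at 120410 ± 29921 and 103620 ± 23343 CPM (-0.22 ± 0.60, edgeR adjusted p = 0.90).

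Smooth muscle and pericyte genes were called lower as a list (10 members, median -0.50, camera adjusted p = 0.0011; adjusted p = 0.11 with an estimated correlation). In it 0 members passed over all genes by edgeR, 3 at an unadjusted p under 0.05, 3 adjusted over the list alone, 3 by DESeq2, 1 by limma-voom and 4 by limma-voom with sample weights. Relative to all genes their median was -0.51, also with library size as the only scaling. MYH11 and TAGLN, contractile proteins of smooth muscle, were at -1.27 ± 0.25 and -1.61 ± 0.39 (edgeR adjusted p = 0.065 and 0.11). Skeletal muscle genes were called lower (8 members, median -0.33, camera adjusted p = 0.032; adjusted p = 0.70 with an estimated correlation). In it 0 passed over all genes by edgeR, 1 at an unadjusted p under 0.05, 1 adjusted over the list alone, 1 by DESeq2, 1 by limma-voom and 2 by limma-voom with sample weights. Relative to all genes their median was -0.34, and -0.42 with library size as the only scaling. The call was lost without control replicate 2 or osteoarthritis replicate 3 or 4 (medians of -0.12, -0.089 and -0.0505). It was also lost under a stricter filter (adjusted p = 0.056), with 1 surrogate variable (adjusted p = 0.86) and by fry (adjusted p = 0.37). The called median was -0.51 without control replicate 1 or 4, -0.14 without osteoarthritis replicate 1 and -1.49 without osteoarthritis replicate 2. In that list ACTN2 was at -1.23 ± 0.23 (edgeR adjusted p = 0.053) and CKM at -0.78 ± 0.64 (edgeR adjusted p = 0.61), the latter at -1.45 without osteoarthritis replicate 2.

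Immune, vascular and stress genes had no list call with all 8 libraries and 0 members that passed over all genes by edgeR. Adjusted over the list alone, 2 members passed for the unfolded protein response, 2 for Schwann cells and nerve, 1 for lymphocytes, 1 for endothelium and 0 for each of the others. Some lists had few tested genes and could show little. These were 3 of 13 listed for neutrophils and granulocytes, 3 of 13 for erythroid cells, 6 of 11 for Schwann cells and nerve, 7 of 11 for adipocytes and 9 of 18 for lymphocytes. List median and camera adjusted p were 0.63 and 0.093 for macrophages and monocytes (CD86 at 2.88 ± 0.56 and 6.57 ± 4.59 CPM), 0.19 and 0.81 for lymphocytes (CD79A -0.85 ± 0.20), 0.27 and 0.93 for neutrophils and granulocytes (CXCR2 0.87 ± 0.92) and -1.96 and 0.75 for erythroid cells (SLC4A1 -2.63 ± 1.70). They were 0.37 and 0.064 for endothelium (MMRN2 0.97 ± 0.23), 1.16 and 0.064 for adipocytes (LPL 1.00 ± 0.33) and -0.53 and 0.080 for Schwann cells and nerve (ERBB3 -0.73 ± 0.18). For stress and growth they were 0.36 and 0.62 for the interferon response (MX2 0.99 ± 0.60), 0.20 and 0.40 for immediate-early and heat-shock genes (ATF3 1.69 ± 0.69), 0.34 and 0.053 for the unfolded protein response (DNAJB9 1.31 ± 0.29) and -0.38 and 0.064 for the cell cycle (AURKA -0.67 ± 0.21). At an unadjusted p under 0.05 there were 3 members for the unfolded protein response, 2 each for immediate-early genes, endothelium and Schwann cells, 1 each for the cell cycle, macrophages, lymphocytes and adipocytes, and 0 for the others. DESeq2 called 2 members for the unfolded protein response, 2 for Schwann cells, 1 for lymphocytes and 1 for endothelium, limma-voom called 0, and limma-voom with sample weights called 0 to 8 per list. Fold changes moved to 0.018 for MX2 without osteoarthritis replicate 4, 0.85 for ATF3 without osteoarthritis replicate 2, and -0.33 for CXCR2 and -4.81 for SLC4A1 without osteoarthritis replicate 3. Without control replicate 4, CXCR2 was at 1.59 and SLC4A1 at 1.49. Several of these lists were called by camera when 1 library was left out, and not in the other such fits. Endothelium was called higher without control replicate 2 or 4 or osteoarthritis replicate 4 (adjusted p = 0.0016, 0.044 and 0.022; otherwise up to 0.45), and its median was 0.060 without osteoarthritis replicate 3. Macrophage genes were called higher without control replicate 4 or osteoarthritis replicate 1 or 2 (adjusted p = 0.0035, 0.030 and 0.045; otherwise up to 0.53), with medians of 0.98 without control replicate 4 and -0.068 without osteoarthritis replicate 3. The unfolded protein response was called higher without control replicate 1 or 3 or osteoarthritis replicate 3 or 4 (adjusted p = 0.0070, 0.0053, 0.017 and 0.038; otherwise up to 0.34), with medians of 0.21 and 0.14 without control replicates 2 and 4. Adipocyte genes were called higher without control replicate 4 or osteoarthritis replicate 4 (adjusted p = 0.042 and 0.013; otherwise up to 0.37), with a median of 0.69 without osteoarthritis replicate 3. The cell cycle was called lower without control replicate 2 or 4 or osteoarthritis replicate 2 or 4 (adjusted p = 0.020, 0.0035, 0.045 and 0.022; otherwise up to 0.46), with medians of -0.21 and -0.20 without control replicates 1 and 3 and -0.18 without osteoarthritis replicate 3. Schwann cells were called lower without control replicate 1 or 3 (adjusted p = 0.026 and 0.030; otherwise up to 0.27), with medians of -0.25 without control replicate 4 and -0.97 without osteoarthritis replicate 3. The interferon response, with a median of -0.52, was called lower without osteoarthritis replicate 4 (adjusted p = 0.012; otherwise up to 0.90). In all, 11 of 27 lists were called at the preset correlation, 1 with an estimated correlation and 6 by fry, which tests whether a list's genes move on balance in a single direction. Of the 16 lists not called, 10 were called in at least 1 fit with a library left out, and 7 of the 11 called lists were called in all 8 such fits.

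Several ribosomal and small nucleolar RNAs had lower counts in osteoarthritis. The libraries were depleted of ribosomal RNA, so counts of ribosomal RNA genes are what depletion left and do not give their levels in the cells. RN18S, the cytosolic 18S ribosomal RNA, fell by 8.13 ± 0.85 on the log2 scale, from 994.2 ± 794.1 to 3.52 ± 2.57 CPM (edgeR adjusted p = 0.0063). It was at -7.42 without control replicate 2 and -8.77 without osteoarthritis replicate 4. The mitochondrial ribosomal RNAs KEF22_r01 and KEF22_r02 fell by 7.76 ± 1.16 and 6.96 ± 1.12 (edgeR adjusted p = 0.031 and 0.037; called in 3 and 2 of 8 fits with a library left out, lost in both genes without control replicate 3 or any of the osteoarthritis replicates). Without control replicate 2 these were at -6.26 for KEF22_r01 and -5.34 for KEF22_r02. SNORA73 (ENSSSCG00000034185), a small nucleolar RNA with near-identical copies, fell by 3.57 ± 0.30 (edgeR adjusted p = 0.0029). Of 29 tested short non-coding and ribosomal RNA genes 9 fell, 23 were below 0 and 6 above, and the median was -2.25 (relative to all genes -2.26, and -1.93 with 9 falling when library size was the only scaling). Of 74 ribosomal protein genes 7 fell, 61 were below 0 and 13 above, and the median was -0.50. Relative to all genes that median was -0.51. With library size as the only scaling the median turned to 0.16, or -0.49 relative to all genes, with 0 falling by edgeR. Their share of counts was 0.976 ± 0.275% in controls and 1.23 ± 0.103% in osteoarthritis (SD, n = 4 each; exact permutation p = 0.0571, adjusted p = 0.0898).

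Short non-coding and ribosomal RNA genes took 16.2 ± 7.87% of counts in controls and 3.11 ± 0.55% in osteoarthritis (SD, n = 4 each; exact permutation p = 0.0286, the smallest possible, adjusted p = 0.063), and mitochondrial rRNA took 5.49 ± 4.58% and 0.0808 ± 0.0424% (exact permutation p = 0.0286, adjusted p = 0.063). Protein-coding genes took 67.0 ± 11.6% and 89.2 ± 1.28%, and the 10 most abundant genes 55.6 ± 12.97% and 35.1 ± 6.18% (exact permutation p = 0.0286 and adjusted p = 0.063 for both). These shares did not overlap between groups, so every gene group above was compared between libraries of different composition. Control replicate 2 stood apart, with 27.9% of counts in short non-coding and ribosomal RNA genes and a scaling factor of 0.42. The first principal component, the axis of largest variation in log2 CPM (39.95%), split the controls. Controls 1 and 3 lay at -100.6 and -101.2, and every other library from 1.14 to 59.7. The second component (25.59%) separated the groups, with controls from -108.1 to -11.1 and osteoarthritis from 32.5 to 50.1. Control replicates 1 and 3 were closer to each other than any other pair, with a chi-square per gene of 2.14 against 14.1 for the next pair. They still differed beyond counting noise. Libraries of 1 animal would do so too, and the labels do not say whether these share an animal, so they were kept as separate samples without evidence that they are independent. With these samples summed into 1, 31 genes changed, 6 higher and 25 lower, and 10 of the 19 changed named genes lost their call, an alternative chosen after seeing the data.

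**Figure D3:**
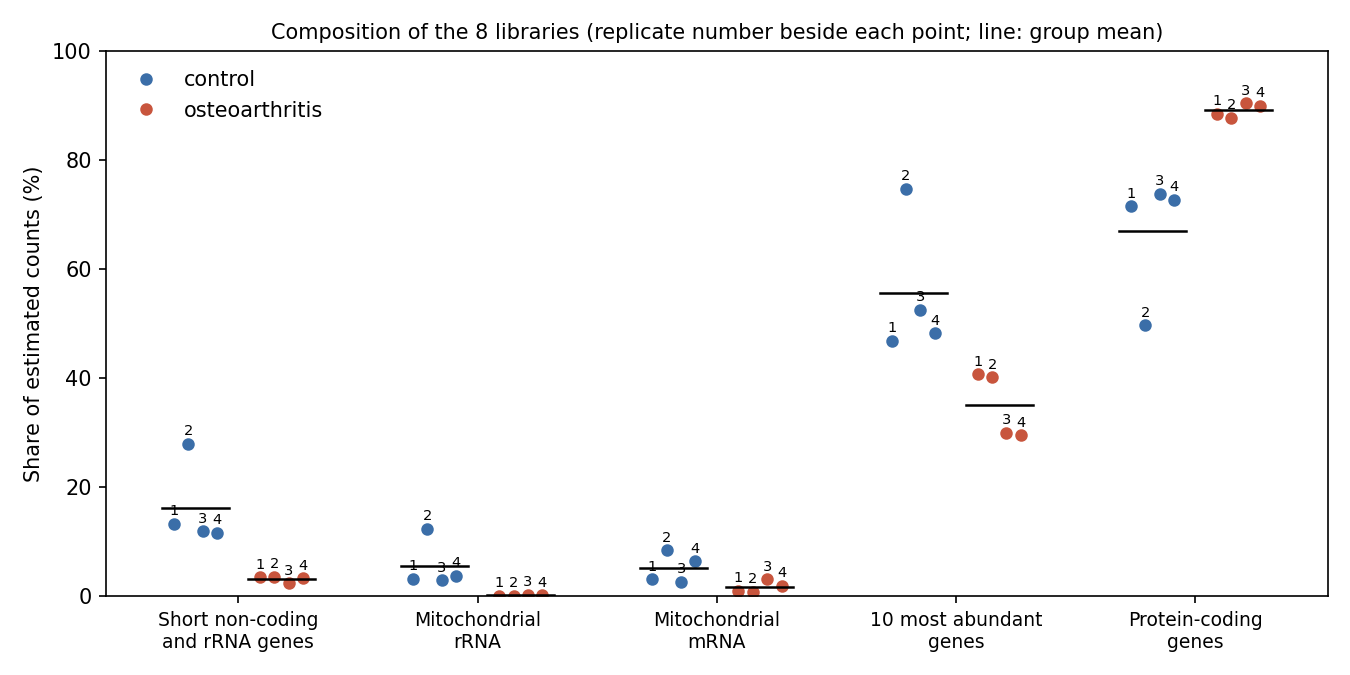
Share of estimated counts (percent, y axis) in 5 gene classes for each library, with replicate numbers beside the points and a line at each group mean. Short non-coding and ribosomal RNA genes take 11.6 to 27.9% in the 4 controls and 2.30 to 3.48% in the 4 osteoarthritis libraries.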

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

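The tests on aberrant controls, on the ratio of mitochondrial RNAs, on mitochondrial content, on the length of ribosomal protein genes and on splits with controls 1 and 3 summed were chosen only after the result was seen. Of these, 2 replaced earlier tests: the fold change of RN18S (-8.13), and the shortest 10% of protein-coding genes, whose median without ribosomal protein genes is -0.081. Tests of total count and of scaling, the latter on the cartilage median of protein-coding genes alone (2.31) and then against all genes, were dropped, as CPM and the comparison with all genes fixed their outcomes.

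A library far from the 3 others of its group was sought in 152 groups of 4, over the named genes and library measures, and found in 15. Chance gives about 5% of groups, or 7.6. Control replicate 2 lay apart in mitochondrial rRNA (KEF22_r01 at 17.27 and KEF22_r02 at 17.02 log2 CPM, and 12.3% of counts), short non-coding and ribosomal RNA (27.9%), protein-coding share (49.7%), MYH11 (5.20 log2 CPM) and CKM (1.75 log2 CPM). Control replicate 4 lay apart in PAPLN (3.18), PAQR9 (3.40) and AXIN2 (2.56 log2 CPM) and in haemoglobin (0.104% of counts). Osteoarthritis replicate 3 lay apart in GDF5 (-0.51) and SLC4A1 (3.71 log2 CPM) and in haemoglobin (0.0331% of counts), and osteoarthritis replicate 1 in CA2 (6.60 log2 CPM).

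The count of 99 changed genes was set against the 35 splits of the 8 samples into 4 and 4. Only 1 split, the real one, gave as many genes, and the highest other count was 12. Chance is thus unlikely for this count, at the smallest share that 35 splits can give, but is not excluded. Those splits treat controls 1 and 3, the closest pair, as separate samples. With their counts summed, 31 genes changed. Only 1 of the 35 splits of the 7 samples into 3 and 4, the real one, gave as many. The highest other count was 9, so chance is unlikely there too. Neither test shows what the changed genes reflect, as library composition also followed the groups. For gene lists, 15 of the 35 splits called at least the 11 lists of the real groups, and the highest other count was 18, so chance cannot be excluded for the number of lists called at the preset correlation.

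Short non-coding and ribosomal RNA genes took 16.2% of counts in controls and 3.11% in osteoarthritis, with 9 of 29 falling, and 7 of 74 ribosomal protein genes fell although their share of counts was 0.976% and 1.23%. The tables argue against mitochondrial content as the origin for mitochondrial rRNA, since the log2 share of mitochondrial mRNA moved by -1.70 against -5.97 for mitochondrial rRNA, a ratio of 0.285. They argue against recovery of short transcripts for ribosomal protein genes, since 641 other protein-coding genes of like length had a median log2 fold change of -0.087 against -0.50. For the 29 short non-coding and ribosomal RNA genes recovery stays open (Spearman rho of 0.034 between length and fold change across genes, which are not independent replicates, permutation p = 0.86). A candidate explanation is rRNA depletion or library preparation, as the log2 ratio of mitochondrial rRNA to mRNA differed by -4.27 without overlap. That ratio contains the fall of mitochondrial rRNA that it is meant to explain, so it is not separate evidence. Counts of ribosomal RNA genes are what depletion left, and do not give levels of these RNAs in the cells. A batch of depletion or preparation would follow the groups and cannot be told apart from the disease, which was not tested.

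Basal epithelial genes were found in all 4 controls, with 0.80 to 0.89 KRT14 counts per KRT5 count. RNA of a basal epithelial source may be present: 16 tested genes, of 40 listed before the test, had a median of -0.37 with 10 below 0. A bound of -0.5, set in advance against such a source, was therefore met, but by less than the standard error of 0.22, and the verdict was changed from against to undecided when the spread was taken into account after the result was seen. Members went both ways. Some, such as DST and EGFR (named after their values were seen), have high levels that would hide a small share, so the listed genes cannot decide. KRT5, KRT14, TP63, SERPINB5 and PKP1 go with such a source, but they are part of the pattern to be explained. The source stays open, as does an untested biological difference.

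Cartilage genes were measured higher in osteoarthritis. The list median was 2.28 to 2.77 over the scalings tried, which does not test scaling as a source. The tables argue against a fault of 1 or 2 controls, as 4 of the 4 controls had a score below every osteoarthritis library. Osteoblast and smooth muscle scores moved apart by 2.51 on the log2 scale (exact permutation p = 0.0286, the smallest possible). This argues only weakly against a larger share of every other cell type together in the controls. The osteoblast score was 4.19 and 4.45 in control replicates 1 and 3, the pair not shown to be independent. It was 6.91 and 7.66 in control replicates 2 and 4, and 7.26 to 8.16 in osteoarthritis. A larger share of only some other cell types in the controls was not tested. The depth or region of tissue sampled was not tested and may play a part, as may the disease or a library batch that follows the groups. The list's call is among the 11 calls at the preset correlation, a number that 15 of 35 splits reached. Whether those splits called this list was not examined.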

How the results depend on the processing

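The fits with controls 1 and 3 summed, with length offsets and on protein-coding genes alone were chosen after seeing the data. The cause of a change was not tested, except that fits with a library left out or summed have fewer samples. The 99 changed genes became 214 with library size as the only scaling, 844 by DESeq2, 3329 by limma-voom with sample weights, 31 against a 1.5-fold change, 7 with 1 surrogate variable, 31 with controls 1 and 3 summed, 15 and 285 at adjusted p under 0.01 and 0.1, and 14 to 152 with a library left out. The other alternatives gave 77 to 122. With the replicate number as a block, 1 gene and 13 lists were called. Secreted Wnt antagonists (camera adjusted p = 0.031) were among them and hedgehog (camera adjusted p = 0.051) was not. Samples of the same number did not deviate together (correlations from -0.32 to -0.019, 0 of 8 samples closest to its own number). The values thus gave no sign of pairing by number. Large differences within a group could hide a pairing, and the labels do not say whether numbers mark pairs, so pairing is not excluded. The 11 called lists became 1 with an estimated correlation and 6 by fry, and 9 to 16 otherwise. Library size alone moved the median of all genes from 0.0049 to 0.65, and with it smooth muscle (0.14) and skeletal muscle (0.23), which relative to all genes stayed lower (-0.51 and -0.42) and called. Under the other alternatives list medians changed sign for 2 called lists and 10 others. With the surrogate variable they became 0.27 for skeletal muscle, 0.25 for canonical Wnt targets, 0.22 for fibroblasts, -0.041 for osteoclasts, -0.65 for interferon (called lower, adjusted p = 0.0067), -0.35 for macrophages, -0.64 for lymphocytes and -0.99 for neutrophils. Ranges with a library left out were -0.0034 to 0.59 for hedgehog, -0.11 to 1.16 for osteoclasts, -0.28 to 0.28 for fibroblasts, -0.27 to 0.29 for inflammation, -0.52 to 0.56 for interferon, -0.029 to 0.57 for immediate-early genes, -0.068 to 0.98 for macrophages, -0.36 to 2.38 for lymphocytes, -0.69 to 0.85 for neutrophils and -3.70 to 1.49 for erythroid cells. Fibroblast, inflammation, lymphocyte and neutrophil medians also changed sign under the filter, block, summed or protein-coding alternatives.

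Of 449 values of the 19 changed named genes under alternatives, 314 kept the call, 135 lost it and 0 reversed. Genes without a call changed sign with the surrogate variable (MX2 -0.29, CD86 -0.032, RUNX1 -0.050, SOST -0.72), with sample weights (SLC4A1 1.31, LEF1 -0.073, SFRP2 -0.77) and with library size alone (COL1A1 0.38, below the median of all genes). With a library left out the ranges were -0.33 to 1.59 for CXCR2, -4.81 to 1.49 for SLC4A1, -0.012 to 0.38 for RUNX1, -0.50 to 0.90 for SFRP2 and -0.72 to 1.61 for SOST.

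Differences of library measures (osteoarthritis minus control) with a library left out were 258.2 to 516.5 for genes detected, -6.29 to -3.13 percentage points for mitochondrial rRNA, -4.28 to -2.36 for mitochondrial mRNA, 0.118 to 0.322 for ribosomal protein genes, -0.0257 to 0.00898 for haemoglobin and -23.4 to -14.2 for the 10 most abundant genes, and -8.89 to 4.37 bases for fragment length. For the total count the difference ranged from 765200 to 5451400. Depth limits LGR5, which was too low to test.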

Other observations

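The genes in this part were chosen after their values were seen, the test on albumin likewise, and the verdict on a hepatic source was changed from against to undecided after the result was seen. Among single genes higher in osteoarthritis, SLC35D1, a nucleotide-sugar transporter of the endoplasmic reticulum, rose by 1.72 ± 0.27 and SLC35B2, a Golgi transporter of the sulphate donor, by 1.29 ± 0.22 on the log2 scale (edgeR adjusted p = 0.037 and 0.044, n = 4 per group). SGMS2, a sphingomyelin synthase active in bone, was at 2.36 ± 0.35, TWSG1, a BMP-binding protein, at 1.82 ± 0.31 and ACKR3, a scavenging chemokine receptor, at 1.56 ± 0.24. SURF6, a nucleolar protein gene, had 59, 38, 70 and 95 counts in the controls and 0 in every osteoarthritis library, at least 176-fold lower against a floor of 3 counts over the group. It was not alone, as SPRP had 120 counts over the controls and 0 over osteoarthritis, and other genes were absent from every control. The cause of such absence from a whole group was not tested.

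AFP and APOB, genes of liver and yolk sac, had 0 counts in every control and 45, 109, 63 and 112 (AFP) and 38, 75, 61 and 83 (APOB) counts in osteoarthritis replicates 1 to 4, at least 71.9-fold and 54.2-fold higher against a floor of 3 counts over the group. APOH had 0 counts in every control and 13, 14, 15 and 22 in osteoarthritis replicates 1 to 4, and SERPINA1 had 0, 0, 0 and 2 in controls and 79, 22, 14 and 19 in osteoarthritis. Absence from every control was not confined to genes of liver, as LAMA2 had 0 counts over the controls and 175 over osteoarthritis. The hypothesis that a hepatic source may add RNA to the osteoarthritis libraries was tested on 13 further hepatocyte genes of 40 listed before the test. Their median log2 fold change was 0.15 with a standard error of 0.37, under a bound of 0.5 set in advance by less than that error, so the list alone did not decide. ALB, the most abundant hepatocyte transcript, was at 2.75 ± 0.40 and 3.02 ± 1.57 CPM, a gain of 0.0644 times that of AFP, which hepatocytes would not give, but 1 gene does not decide while APOH and SERPINA1 go with such a source, so it stays open.

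KDM5D, a Y-linked gene, had 140, 0, 114 and 10 counts in control replicates 1 to 4 and 6, 2, 657 and 509 counts in osteoarthritis replicates 1 to 4. EIF1AY, also Y-linked, had 29, 0, 38 and 7 counts in controls and 0, 2, 69 and 119 in osteoarthritis. Y-linked counts thus varied within both groups, and sex was not a term of the fit. DMP1, a gene of osteocytes, had 73, 3774, 51 and 11731 counts in controls and 3791, 2268, 21781 and 9253 in osteoarthritis.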
